A study of Mus musculus with 15 samples.

How the data were processed

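Total RNA from 15 cultures of G1E cells was measured on Affymetrix mouse arrays, 3 biological replicates of each of 5 lines (GATA1-ER wild type, R216Q, R216W, D218G and D218Y), all after 100 nM estradiol for 24 hours. The group and replicate number of each array came from its title in the labels. How many separately transduced lines or pools stand behind each construct is not given in the sources used here, so each mutation was taken as 1 line: line and mutation cannot be told apart, and p-values measure the spread between these cultures. Processing dates were not used here.

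The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, the authors used Partek 6.6 and RMA, which corrects background, normalizes arrays by quantiles and summarises probes. Settings and the RMA version are not given in the sources used here. The deposited log2 values were used unchanged, with no filter on low values and no further scaling. Array values carry no counts, so the number of arrays, not a depth, limits the precision. RMA makes the array distributions alike, and it compresses fold changes of dim genes, so a change near the lowest values is understated.

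The table held 28350 probe sets, of which 21780 had 1 gene symbol in the platform annotation, 1618 had several and 4952 had none listed. The gene identifier of 21689 probe sets matched the RefSeq gene table, and 0 symbols changed. Genes were named from probe sets with 1 symbol alone, taking the probe set with the highest mean over all arrays where a gene had several (996 genes), which gave 19933 genes tested. The adult alpha- and beta-globin genes were for this reason not analysed here. No coordinates were used.

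Differences were tested with limma 3.58.1 in R 4.3.3: lmFit with 1 mean per line over all 15 arrays, contrasts, eBayes without trend, and Benjamini-Hochberg adjustment over all genes tested within a contrast, with calls at an adjusted p under 0.05 (two-sided). The 7 contrasts were each mutant against wild type, R216W against R216Q, D218Y against D218G, and the mean of the D218 lines against the mean of the R216 lines. The F test asked whether any line differed. Errors of log2 fold changes are limma's moderated standard errors (SE). Gata1 was also tested with an exact permutation test. The text uses rose and fell for members of a list with an adjusted p under 0.05 over all genes tested. Counts adjusted over the list alone repeat the adjustment within the list.

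There were 21 gene lists, fixed with the tests, the naming rule and most alternatives before the data were examined: globin, haem synthesis, iron handling, red cell membrane, erythroid regulators, progenitor genes, mast cell, megakaryocyte, granulocyte and monocyte, lymphoid, stroma, S phase, mitosis, restraint of the cell cycle, Myc and ribosome biogenesis, the Bcl2 family, autophagy, sterol synthesis, glycolysis, early stress response and interferon response. Lists were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists of a contrast, and again with the correlation estimated from the residuals. Camera compares a list with all other genes.

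Genes were named by a rule: Gata1; the 10 largest rises and the 10 largest falls per contrast among genes past the threshold whose arrays did not overlap between the groups, passing over placeholder symbols and small RNAs; up to 4 members per list with the largest changes past the threshold; and a fixed set of erythroid, progenitor and megakaryocyte genes. A largest rise or fall in the text is the largest under this rule.

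The fit and list test were first tested on simulated data with 19933 genes, the real gene means and spreads, and 50 genes changed at each of 4 sizes per contrast. In the simulated D218Y contrast 0% of genes changed by 0.1 (log2) were called, 42% of those changed by 0.25, 98% of those changed by 0.5 and 100% of those changed by 1, with 3 false calls, and the planted list was called with 0 others. For R216Q the shares were 2%, 50%, 96% and 100% with 7 false calls. The simulated genes varied independently of each other. The simulation therefore cannot show how often the list test calls a list of correlated genes falsely. Few genes were changed in it, whereas 44.4% passed in the real D218Y contrast, and fewer changed genes make the adjusted threshold stricter. The shares recovered thus do not give the sensitivity of the real contrasts, where the smallest change called in D218Y was 0.08.

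Alternatives, changed singly, were quantile and cyclic loess normalization, genes above the median intensity alone, the arrays of the compared groups alone, eBayes with trend and robust, no moderation, array weights, the replicate number as a block, an adjusted p under 0.01, a 2-fold threshold, every probe set, the mean of a gene's probe sets, other list tests (fry, and camera on ranks) and each array left out in turn. The array median as a covariate, and replicate 3 of D218G left out of all comparisons, were added after the data were seen. Overlaps between mutants were set beside 100 simulations of unchanged groups against the same wild type arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.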

Results

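The series held 15 mouse arrays from G1E cells, an immature erythroid line that lacks functional GATA1, the transcription factor needed for red cell and megakaryocyte maturation. Each line carried GATA1 fused to an estrogen receptor domain, either wild type or with the amino acid change R216Q, R216W, D218G or D218Y. The changed residues lie in the amino-terminal zinc finger, which contacts DNA and the cofactor FOG1 (gene Zfpm1). All cells had received 100 nM estradiol for 24 hours, which switches the fusion protein on. The reference throughout was the induced wild type line, and untreated cells were not analysed here. There were 5 lines with 3 biological replicates each. The values were log2 RMA values, which ran from 2.89 to 13.58, with array medians between 6.24 and 6.41. The median standard deviation of a gene within a line was 0.06 for wild type, 0.05 for R216Q, R216W and D218Y, and 0.08 for D218G. The number of arrays limits the precision of every comparison.

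The 5 lines separated from each other in expression. The first principal component held 58.8% of the variance and ran from -22.49 in a wild type array to 37.11 in a D218Y array. On the second component, with 17.0% of the variance, the R216W arrays lay between 16.49 and 17.18 and the D218G arrays between -17.14 and -11.38. Replicate 3 of D218G stood apart from the other arrays of its line, at 12.75 on the third component against -2.32 and -6.44, and its array median was 6.24 against 6.37 and 6.40. Of 19933 genes tested, 8347 differed among the 5 lines by limma's F test.

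**Figure D1:**
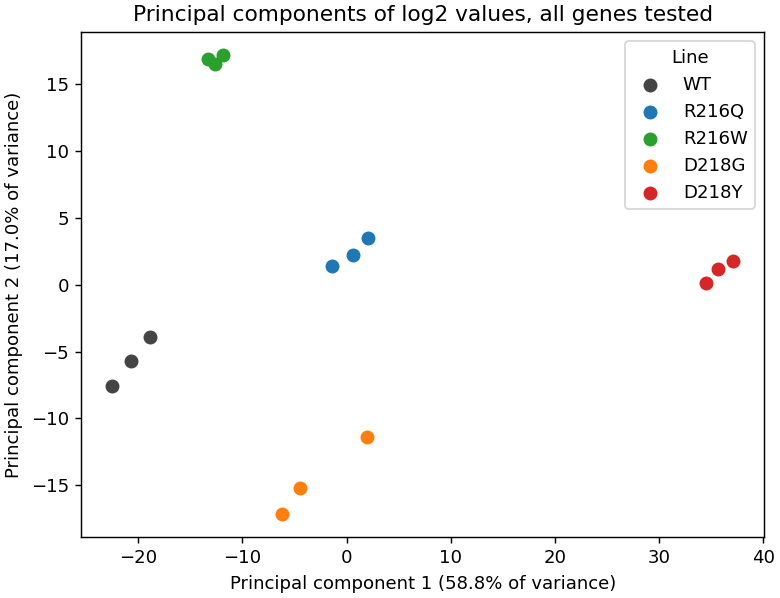
Principal components 1 and 2 of the log2 values of all genes tested, with 1 point per array and a colour per line; the axis labels give each component's share of the variance (58.8% and 17.0%). The D218Y arrays sit alone above 34.53 on the first component, and the R216W and D218G arrays lie at opposite ends of the second.

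Gata1 transcript itself was near the top of the array range in every line. The wild type arrays read 12.35 to 12.36 (mean 12.36 ± 0.01 SD, n = 3). Gata1 was lower in D218Y (log2 fold change -0.29 ± 0.03 SE, adjusted p = 1.12e-06, 18.3% lower) and in R216Q (-0.21 ± 0.03, adjusted p = 1.08e-04). In R216W Gata1 was at -0.11 ± 0.03 (adjusted p = 0.022). This call was lost when any single array of either line was left out (adjusted p from 0.0512 to 0.0719) or when only these 6 arrays were fitted (adjusted p = 0.102). In D218G Gata1 was at -0.00 ± 0.03 (adjusted p = 0.961). An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1, the smallest it allows, for R216Q, R216W and D218Y, and p = 0.8 for D218G. The probe set was not checked against the disrupted allele, so transcript from that allele is not told apart from the fusion.

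In R216Q cells, red cell genes were lower than in wild type, while Kit and Gata2 were higher and the other progenitor genes went both ways. Slc4a1, the band 3 anion exchanger of the red cell membrane, fell by 1.06 ± 0.05 on the log2 scale (SE, n = 3 per line, adjusted p = 2.52e-09), and the embryonic globin gene Hba-x fell by 1.99 ± 0.07 (adjusted p = 1.3e-10). Kit, the stem cell factor receptor, rose by 1.45 ± 0.04 and Gata2, a progenitor transcription factor, by 1.17 ± 0.04. The zinc transporter gene Slc30a2 (3.38 ± 0.08) and Tph1, the first enzyme of serotonin synthesis (2.58 ± 0.07), had the largest rises. Slc22a4, a cation transporter gene, had the largest fall among the genes named (-2.27 ± 0.06), followed by Hba-x and Tmod3, a capping protein of actin filaments (-1.81 ± 0.04).

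Among 11 measured haem synthesis genes 9 fell and none rose in R216Q, with the same counts adjusted over the list alone (median -0.27, adjusted p = 5.26e-08). They included Uros (-0.86 ± 0.04), Slc25a39 (-0.65 ± 0.03), Alad (-0.35 ± 0.03) and Alas2, the first enzyme of the erythroid pathway (-0.31 ± 0.06). Of 23 red cell membrane genes 13 fell and 1 rose, or 15 and 2 adjusted over the list alone (median -0.16, adjusted p = 5.26e-08). Among them were Tmod1 (-1.43 ± 0.06), Dmtn (-1.07 ± 0.05) and Epb42 (-1.06 ± 0.08). Of 5 measured globin genes 3 fell, also adjusted over the list alone, with Hbb-y at -1.13 ± 0.11. The globin genes measured were Hba-x, Hbb-bh1, Hbb-y, Hbq1a and Hbq1b, with no adult alpha- or beta-globin gene among them. Of 26 erythroid regulators 13 fell and 3 rose, or 17 and 3 adjusted over the list alone (adjusted p = 1.77e-06). Trim10 (-0.73 ± 0.03) and Nfe2 (-0.70 ± 0.04) were among those that fell, whereas Klf1 (-0.09 ± 0.04) and Zfpm1 (-0.07 ± 0.03) did not pass. Of 29 Myc and ribosome biogenesis genes 28 rose and none fell, or 29 adjusted over the list alone (median 0.41, adjusted p = 7.19e-26). They included Rrp9 (0.77 ± 0.05) and Srm (0.66 ± 0.05), and Myc itself rose by 0.31 ± 0.05. Of 17 glycolysis genes 14 rose and 1 fell, also adjusted over the list alone (median 0.53), led by Pfkp (1.40 ± 0.06) and Pgam1 (1.39 ± 0.06). Of 25 mitosis genes 18 fell and none rose, or 21 adjusted over the list alone (median -0.23), including Cenpf (-0.52 ± 0.04) and Birc5 (-0.40 ± 0.03). All of these lists also passed with an estimated correlation (adjusted p from 0.0032 for haem synthesis to 0.0485 for erythroid regulators).

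A further 4 lists were lower in R216Q with the preset correlation alone. Of 15 iron handling genes 8 fell and 1, Hmox1, rose (1.17 ± 0.09), also adjusted over the list alone (adjusted p = 9.56e-04; adjusted p = 0.0583 with an estimated correlation). Of 25 S phase genes 14 fell and 1 rose, also adjusted over the list alone (adjusted p = 1.06e-05; adjusted p = 0.156 with an estimated correlation). Of 22 autophagy genes 9 fell and 3 rose, or 10 and 3 adjusted over the list alone (adjusted p = 0.0147; adjusted p = 0.262 with an estimated correlation). Bnip3, a mitophagy receptor, was among the 3 that rose (1.43 ± 0.12). Of 19 megakaryocyte genes 4 fell, also adjusted over the list alone (adjusted p = 0.0028; adjusted p = 0.159 with an estimated correlation). They were Tubb1 (-1.74 ± 0.09), Gp9 (-1.61 ± 0.06), Plek (-1.57 ± 0.08) and Itgb3 (-0.45 ± 0.05). Of 25 progenitor genes 7 rose and 4 fell, also adjusted over the list alone, with Hhex at 1.54 ± 0.10 and Cd44 at 1.22 ± 0.05. The list as a whole did not pass (median -0.03, mean 0.17, adjusted p = 0.17). By limma with Benjamini-Hochberg adjustment, 4283 genes differed between R216Q and wild type, 2359 higher and 1924 lower, and 100 of them by at least 2-fold (55 higher, 45 lower).

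In R216W cells, Gata2, Hhex and Kit, genes of immature progenitors, were higher than in wild type, while the fall of red cell genes differed from gene to gene. Gata2 rose by 1.26 ± 0.04 (SE, n = 3 per line, adjusted p = 6.56e-11), Hhex, a homeobox gene of early blood cells, by 1.35 ± 0.10, and Kit by 0.84 ± 0.04. Epb42, the band 4.2 membrane protein, fell by 0.97 ± 0.08 (adjusted p = 4.52e-07) and Dmtn, the actin-bundling protein dematin, by 1.03 ± 0.05, whereas Slc4a1 was at -0.12 ± 0.05 and did not pass (adjusted p = 0.145). Slc30a2 (3.39 ± 0.08) and Tph1 (2.65 ± 0.07) had the largest rises, followed by Nceh1 (2.22 ± 0.08), the interleukin 4 receptor gene Il4ra (2.18 ± 0.06) and Rnd2 (2.15 ± 0.05). The interleukin 9 receptor gene Il9r rose by 1.79 ± 0.05. Tubb1, the tubulin of platelets, had the largest fall (-2.26 ± 0.09), followed by Pkhd1l1 (-1.93 ± 0.06).

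Of 25 progenitor genes 11 rose and 1 fell in R216W, or 11 and 2 adjusted over the list alone (median 0.01, mean 0.23, adjusted p = 1.16e-04; adjusted p = 0.0504 with an estimated correlation). The list did not pass on ranks either (adjusted p = 0.107), and the gene that fell was Spi1, the myeloid factor PU.1 (-0.78 ± 0.10). Of 11 haem synthesis genes 6 fell, or 9 adjusted over the list alone (median -0.12, adjusted p = 1.02e-06), including Uros (-0.86 ± 0.04), Ppox (-0.76 ± 0.04) and Alas2 (-0.39 ± 0.06). Of 5 globin genes 4 fell, also adjusted over the list alone (median -0.53), with Hbb-y at -1.02 ± 0.11, Hbb-bh1 at -0.94 ± 0.10 and Hba-x at -0.53 ± 0.07. The haem synthesis and globin lists were those that passed with an estimated correlation (adjusted p = 0.0059 and adjusted p = 0.0456 with an estimated correlation). Of 17 sterol synthesis genes 10 rose and none fell, or 11 and 1 adjusted over the list alone (median 0.18, adjusted p = 2.87e-06; adjusted p = 0.123 with an estimated correlation), led by Hmgcs1 (0.65 ± 0.05) and Mvd (0.41 ± 0.04). Of 17 glycolysis genes 10 rose and 2 fell, or 11 and 2 adjusted over the list alone (adjusted p = 9.29e-07; adjusted p = 0.143 with an estimated correlation), including Pgam1 (1.17 ± 0.06) and Pdk1 (1.04 ± 0.08). The ribosome biogenesis list rose by a small amount, at 10 of 29 genes with 2 lower, or 15 and 3 adjusted over the list alone (median 0.11, adjusted p = 6.04e-04; adjusted p = 0.243 with an estimated correlation). In that list Nop56 fell by 0.30 ± 0.03. Of 25 mitosis genes 15 fell, or 20 adjusted over the list alone (adjusted p = 1.17e-09; adjusted p = 0.0943 with an estimated correlation).

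Red cell membrane genes went both ways in R216W, with 9 of 23 lower and 4 higher, or 12 and 4 adjusted over the list alone (adjusted p = 0.0062; adjusted p = 0.193 with an estimated correlation). Among them Cd59a, an inhibitor of complement, rose by 1.15 ± 0.08. Of 26 erythroid regulators 11 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.003; adjusted p = 0.219 with an estimated correlation), including E2f2 (-0.41 ± 0.05) and Gfi1b (-0.40 ± 0.03). Of 25 S phase genes 8 fell and 1 rose, or 11 and 1 adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.268 with an estimated correlation). Of 15 iron handling genes 7 fell and 2 rose, or 7 and 3 adjusted over the list alone (adjusted p = 0.0231; adjusted p = 0.219 with an estimated correlation). That call was also lost without replicate 2 of wild type (adjusted p = 0.114) and when only these 6 arrays were fitted (adjusted p = 0.0853). On ranks the red cell membrane and iron handling calls were lost as well (adjusted p = 0.113 and 0.185). In all, 3308 genes differed between R216W and wild type, 1866 higher and 1442 lower, and 90 by at least 2-fold (55 higher, 35 lower).

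In D218G cells, sterol synthesis genes and red cell membrane genes were lower than in wild type and ribosome biogenesis genes were higher, while Gata2 moved little. Slc4a1 fell by 1.11 ± 0.05 (SE, n = 3 per line, adjusted p = 4.24e-09), Hba-x by 2.03 ± 0.07 and Epb42 by 0.99 ± 0.08. Gata2 fell by 0.29 ± 0.04 (adjusted p = 1.79e-04), while Kit rose by 0.55 ± 0.04, Myb, a progenitor transcription factor, by 0.88 ± 0.03 and Myc by 0.48 ± 0.05. Of 25 progenitor genes 7 rose and 5 fell, or 8 and 7 adjusted over the list alone. That list did not pass (median -0.03, camera adjusted p = 0.4025). The glutathione transferase gene Gsta4 had the largest rise (1.72 ± 0.07), followed by Ctsl, the lysosomal protease cathepsin L (1.46 ± 0.04). Slc22a4 had the largest fall (-2.42 ± 0.06), and Il9r fell by 1.42 ± 0.05.

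All 17 measured sterol synthesis genes fell in D218G, also adjusted over the list alone (median -0.36, adjusted p = 3.71e-19), including Hmgcs1 (-0.91 ± 0.05), Cyp51 (-0.76 ± 0.06), Idi1 (-0.66 ± 0.06) and Msmo1 (-0.62 ± 0.04). All 29 ribosome biogenesis genes rose, also adjusted over the list alone (median 0.41, adjusted p = 2.86e-33), led by Srm (0.79 ± 0.05) and Odc1 (0.66 ± 0.04). Of 23 red cell membrane genes 16 fell and 1 rose, or 18 and 1 adjusted over the list alone (median -0.20, adjusted p = 6.77e-11), including Slc14a1, the red cell urea transporter (-1.40 ± 0.07), and Tmod1 (-0.80 ± 0.06). Of 11 haem synthesis genes 7 fell and 1 rose, or 8 and 2 adjusted over the list alone (median -0.20, adjusted p = 4.96e-05), with Alas2 at -0.54 ± 0.06. Of 21 genes that restrain the cell cycle 14 fell and 1 rose, or 15 and 1 adjusted over the list alone (median -0.19, adjusted p = 1.11e-06). They included Btg2 (-0.77 ± 0.04) and Gadd45a (-0.76 ± 0.06), whereas Tob1 rose by 0.49 ± 0.05. These 5 lists also passed with an estimated correlation, at adjusted p from 0.0042 for ribosome biogenesis to 0.0071 for the cell cycle genes.

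The other lists that passed in D218G did so with the preset correlation alone. Of 5 globin genes 3 fell, also adjusted over the list alone (adjusted p = 0.0025; adjusted p = 0.0757 with an estimated correlation). Of 17 glycolysis genes 8 rose and 2 fell, or 8 and 3 adjusted over the list alone (adjusted p = 4.96e-05; adjusted p = 0.181 with an estimated correlation), led by Pfkm, the muscle form of phosphofructokinase (1.16 ± 0.04). Of 25 mitosis genes 12 fell and none rose, or 14 and 1 adjusted over the list alone (adjusted p = 3.99e-06; adjusted p = 0.181 with an estimated correlation). Of 22 autophagy genes 8 fell, or 9 with 1 higher adjusted over the list alone (adjusted p = 0.0019; adjusted p = 0.181 with an estimated correlation). Of 19 megakaryocyte genes 5 fell and 1 rose, or 6 and 1 adjusted over the list alone (adjusted p = 0.003; adjusted p = 0.181 with an estimated correlation), with Plek at -1.55 ± 0.08 and Tubb1 at -1.25 ± 0.09. Of 26 erythroid regulators 11 fell and 4 rose, or 12 and 4 adjusted over the list alone (adjusted p = 0.0239; adjusted p = 0.347 with an estimated correlation). In that list E2f4, needed for red cell maturation, rose by 0.53 ± 0.04. The regulators' call was also lost without replicate 1 of D218G (adjusted p = 0.102), and the globin and megakaryocyte calls on ranks (adjusted p = 0.0615 and 0.143). In all, 3601 genes differed between D218G and wild type, 2053 higher and 1548 lower, and 44 by at least 2-fold (19 higher, 25 lower). The count was 3598 without replicate 3 of D218G, the array that stood apart, with 1759 higher and 1839 lower, so the side with more calls turned, and it was 2106 when only the 6 arrays of these lines were fitted.

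In D218Y cells, red cell genes were far lower than in wild type, and the progenitor genes Gata2, Hhex, Kit and Myb were higher. Slc4a1 fell by 5.60 ± 0.05 (SE, n = 3 per line, adjusted p = 2.12e-17) and Tmod1, which caps actin in the red cell membrane skeleton, fell by 3.65 ± 0.06. Alas2 fell by 3.18 ± 0.06 (adjusted p = 1.64e-14), and Erfe, the hormone erythroferrone, fell by 3.24 ± 0.04. Gata2 rose by 2.85 ± 0.04 (adjusted p = 2.29e-15), Hhex by 3.16 ± 0.10, Kit by 2.03 ± 0.04, Myb by 1.85 ± 0.03 and Myc by 1.13 ± 0.05. Erv3, an endogenous retroviral gene, had the largest rise (4.76 ± 0.09), followed by Gask1b (3.59 ± 0.09) and Ehf, an Ets family factor (3.58 ± 0.07). The transcription factor genes Klf1 (-0.28 ± 0.04), Zfpm1 (-0.25 ± 0.03) and Tal1 (-0.82 ± 0.04) fell by less than the red cell genes named.

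**Figure D2:**
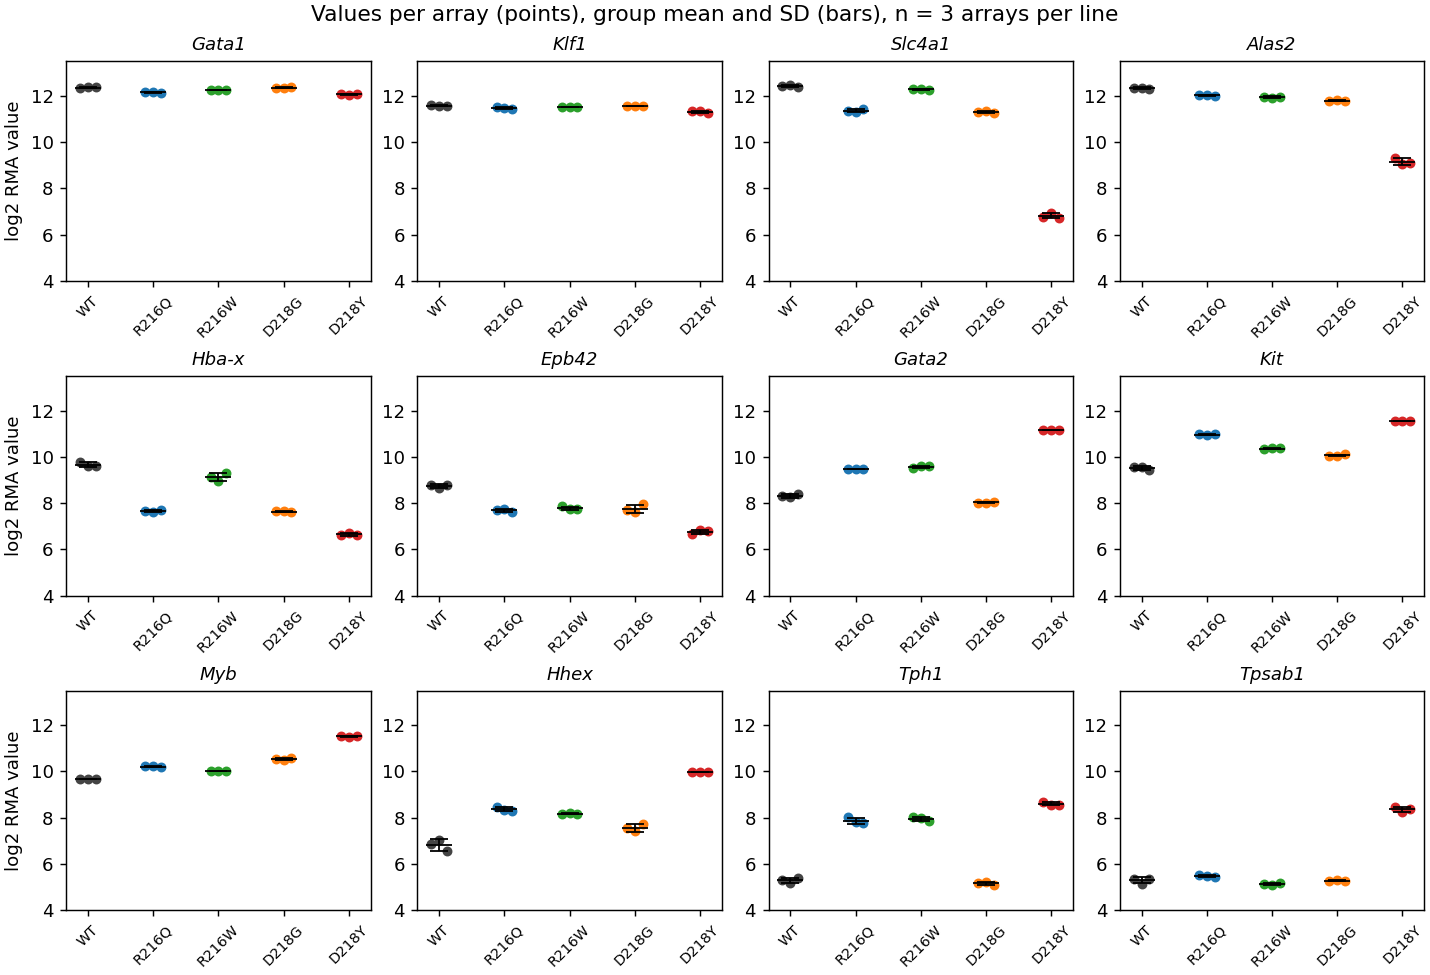
Log2 RMA values of 12 genes in the 5 lines, with 1 point per array, a horizontal bar at the mean and whiskers of 1 SD (n = 3 arrays per line). Slc4a1 and Alas2 are lowest in D218Y, Gata2 is higher in R216Q, R216W and D218Y than in wild type and slightly lower in D218G, and Tpsab1 stands out in D218Y.

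Of 11 haem synthesis genes 10 fell and 1 rose in D218Y, also adjusted over the list alone (median -1.07, adjusted p = 2.22e-08), with Uros at -1.65 ± 0.04 and Abcb10 at -1.31 ± 0.04. Of 23 red cell membrane genes 18 fell and 2 rose, also adjusted over the list alone (median -0.63, adjusted p = 6.63e-10), including Dmtn (-2.91 ± 0.05) and Epb42 (-1.99 ± 0.08). All 5 measured globin genes fell, also adjusted over the list alone (median -1.91), from Hba-x (-3.00 ± 0.07) to Hbb-bh1 (-1.76 ± 0.10) among those named. The adult alpha- and beta-globin genes were not among them. All 29 ribosome biogenesis genes rose, also adjusted over the list alone (median 0.96, adjusted p = 1.69e-25), including Rrs1 (1.48 ± 0.11) and Rrp9 (1.43 ± 0.05). Of 25 mitosis genes 23 fell and none rose, or 24 adjusted over the list alone (median -0.43, adjusted p = 1.13e-10), including Cdc25c (-1.14 ± 0.04) and Cenpf (-1.08 ± 0.04). Of 21 genes that restrain the cell cycle 18 fell and 2 rose, also adjusted over the list alone (median -0.37, adjusted p = 7.27e-05). Gadd45a was at -1.62 ± 0.06 and Cdkn2c at -1.13 ± 0.05, and Tob1 rose by 1.66 ± 0.05. Of 25 progenitor genes 11 rose and 4 fell, or 13 and 4 adjusted over the list alone (median 0.16, adjusted p = 5.03e-04), with Cd44 at 2.05 ± 0.05. These 7 lists passed with an estimated correlation too, at adjusted p from 0.0025 for haem synthesis to 0.0451 for mitosis.

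The remaining lists that passed in D218Y did so with the preset correlation alone. Of 17 glycolysis genes 14 rose and 2 fell, also adjusted over the list alone (median 0.57, adjusted p = 6.35e-07; adjusted p = 0.115 with an estimated correlation), led by Hk2 (2.59 ± 0.09) and Pgam1 (1.90 ± 0.06). Of 26 erythroid regulators 17 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0047; adjusted p = 0.214 with an estimated correlation), with Trim10 at -1.70 ± 0.03 and Klf3 at -0.92 ± 0.03. Of 22 autophagy genes 13 fell and 4 rose, also adjusted over the list alone (adjusted p = 0.0047; adjusted p = 0.214 with an estimated correlation). Calcoco1 fell by 1.10 ± 0.05 while Bnip3 rose by 1.31 ± 0.12. Of 25 S phase genes 15 fell and 3 rose, or 15 and 4 adjusted over the list alone (adjusted p = 0.0056; adjusted p = 0.325 with an estimated correlation). Of 15 iron handling genes 8 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0408; adjusted p = 0.214 with an estimated correlation). The mitochondrial iron importer gene Slc25a37 (-2.33 ± 0.03) and Abcb6 (-1.28 ± 0.04) fell, while Hmox1, which breaks down haem, rose by 1.97 ± 0.09. Of 19 megakaryocyte genes 7 fell and 2 rose, also adjusted over the list alone (adjusted p = 0.0405; adjusted p = 0.317 with an estimated correlation), with Tubb1 at -2.82 ± 0.09 and Itgb3 at -1.91 ± 0.05.

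Mast cell genes also moved in D218Y, and these are markers of another cell type. Of 19 measured, 7 rose and 3 fell, also adjusted over the list alone (median -0.01, mean 0.54, adjusted p = 0.0391; adjusted p = 0.21 with an estimated correlation). Those that rose included Tph1 (3.30 ± 0.07), the tryptase gene Tpsab1 (3.06 ± 0.06), the IgE receptor gene Ms4a2 (2.46 ± 0.08), Hdc, which makes histamine (1.11 ± 0.06), and Cpa3, a mast cell protease (0.65 ± 0.07). The lists for granulocytes and monocytes (adjusted p = 0.776), lymphoid cells (adjusted p = 0.194), stroma (adjusted p = 0.351), interferon response (adjusted p = 0.491), early stress response (adjusted p = 0.709), sterol synthesis (adjusted p = 0.194) and the Bcl2 family (adjusted p = 0.942) did not pass. The sterol list did pass after quantile (adjusted p = 0.0485) and cyclic loess normalization (adjusted p = 0.0217). Single members of the last lists moved all the same, with Egr1 at 2.37 ± 0.06, Dusp1 at -1.98 ± 0.04, Usp18 at 1.09 ± 0.05 and Bcl2l1 at -0.59 ± 0.03.

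By limma with Benjamini-Hochberg adjustment, 8857 genes differed between D218Y and wild type, 4042 higher and 4815 lower, and 711 by at least 2-fold (471 higher, 240 lower). The share of calls that were higher was 45.6%, and it was 55.3% after cyclic loess normalization and 54.2% at an adjusted p under 0.01, so the side with more calls turned. The megakaryocyte call was lost after either other normalization (adjusted p = 0.0587 after quantile normalization and 0.0607 after cyclic loess) and with the array median as a covariate (adjusted p = 0.0615). The iron handling, mast cell and megakaryocyte calls were lost on ranks (adjusted p = 0.169, 0.143 and 0.103) and when only these 6 arrays were fitted (adjusted p = 0.112, 0.0598 and 0.0526). The iron handling and mast cell calls were also lost when arrays were weighted (adjusted p = 0.068 and 0.0556), and the iron handling call was lost without replicate 2 of wild type (adjusted p = 0.105) or without replicate 3 of D218G (adjusted p = 0.068).

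**Figure D3:**
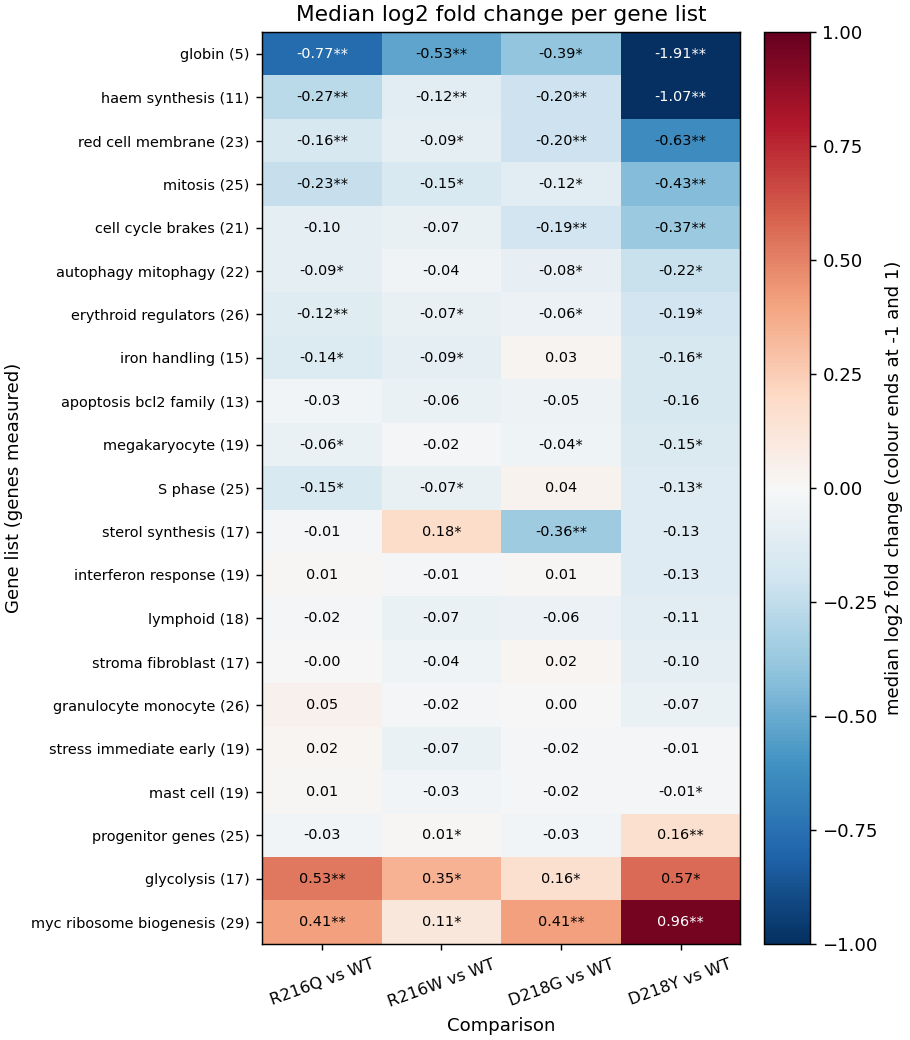
Median log2 fold change of each gene list against wild type (colour and number, colour ending at -1 and 1), with the number of genes measured in brackets and 1 column per mutant. A single star marks lists that passed camera at a preset correlation of 0.01 and a double star those that passed with an estimated correlation as well; ribosome biogenesis is highest in D218Y (0.96) and globin lowest (-1.91).

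R216W and R216Q change the same residue, and their cells differed most in ribosome biogenesis genes among the lists. Of 29 genes 24 fell in R216W relative to R216Q and none rose, or 26 adjusted over the list alone (median -0.32, adjusted p = 1.39e-22; adjusted p = 0.0182 with an estimated correlation). Rrp9 was at -0.72 ± 0.05, Srm at -0.52 ± 0.05 and Odc1 at -0.47 ± 0.04 (SE, n = 3 per line), and Myc was lower too (-0.43 ± 0.05). Slc4a1 (0.94 ± 0.05), Hba-x (1.47 ± 0.07), Slc14a1 (1.81 ± 0.07) and Tmod1 (0.89 ± 0.06) were higher in R216W, whereas Hbb-bh1 was lower (-0.95 ± 0.10). Kit (-0.61 ± 0.04) and Cd44 (-0.62 ± 0.05) were lower in R216W, while Gata2 (0.09 ± 0.04), Alas2 (-0.08 ± 0.06) and Epb42 (0.09 ± 0.08) did not pass. The phospholipase gene Pla2g4c (2.37 ± 0.06) and Rgs18, a regulator of G protein signalling (2.33 ± 0.11), had the largest rises, and Phlda1 (-1.84 ± 0.05) and Foxh1 (-1.79 ± 0.07) the largest falls.

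Sterol synthesis was higher in R216W than in R216Q at 10 of 17 genes with none lower, or 12 adjusted over the list alone (adjusted p = 5.51e-08; adjusted p = 0.15 with an estimated correlation), led by Hmgcs1 (0.61 ± 0.05) and Idi1 (0.56 ± 0.06). Glycolysis was lower at 9 of 17 genes with 1 higher, or 10 and 2 adjusted over the list alone (adjusted p = 0.0013; adjusted p = 0.347 with an estimated correlation), and Pfkm had the largest fall among them (-1.25 ± 0.04). Red cell membrane genes were higher at 8 of 23 and lower at 4, or 10 and 4 adjusted over the list alone (adjusted p = 0.0115; adjusted p = 0.305 with an estimated correlation). Megakaryocyte genes were higher at 5 of 19 and lower at 2, or 6 and 2 adjusted over the list alone (adjusted p = 0.0194; adjusted p = 0.336 with an estimated correlation), with Plek at 1.34 ± 0.08 and Gp9 at 1.07 ± 0.06. Erythroid regulators were higher at 11 of 26 and lower at 5, or 13 and 7 adjusted over the list alone (adjusted p = 0.0194; adjusted p = 0.357 with an estimated correlation). Mitosis genes were higher at 7 of 25 and lower at 2, also adjusted over the list alone (adjusted p = 0.0194; adjusted p = 0.471 with an estimated correlation). Stress genes were lower at 3 of 19, Egr1, Ddit3 and Trib3, and higher at 1, also adjusted over the list alone (adjusted p = 0.0194; adjusted p = 0.305 with an estimated correlation). In all, 3369 genes differed, 1644 higher and 1725 lower in R216W (1830 and 1817 after cyclic loess normalization), and 76 by at least 2-fold (45 higher, 31 lower). Among genes above the median intensity alone, the calls for red cell membrane (adjusted p = 0.0979), erythroid regulators and mitosis (both adjusted p = 0.11) and stress (adjusted p = 0.131) were lost. On ranks the calls for red cell membrane (adjusted p = 0.0723), erythroid regulators (adjusted p = 0.299) and megakaryocyte genes (adjusted p = 0.185) were lost. The mitosis call was also lost without replicate 3 of R216Q (adjusted p = 0.0662) and without moderation (adjusted p = 0.111), and the regulators' call with weighted arrays (adjusted p = 0.055).

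D218Y and D218G change the same residue, and D218Y had lower red cell genes and higher Gata2, Hhex and Kit than D218G. Slc4a1 was at -4.49 ± 0.05 (SE, n = 3 per line, adjusted p = 4.64e-16), Alas2 at -2.65 ± 0.06, Tmod1 at -2.85 ± 0.06 and Hba-x at -0.98 ± 0.07. Gata2 was higher by 3.14 ± 0.04 (adjusted p = 1.73e-15), Hhex by 2.42 ± 0.10, Spi1 by 1.56 ± 0.10 and Kit by 1.47 ± 0.04. Erv3 (4.88 ± 0.09), Tph1 (3.44 ± 0.07) and the tachykinin gene Tac2 (3.33 ± 0.09) had the largest rises. Gata1 was lower in D218Y (-0.29 ± 0.03), as were Klf1 (-0.28 ± 0.04) and Tal1 (-0.69 ± 0.04).

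Of 11 haem synthesis genes 10 were lower in D218Y than in D218G, also adjusted over the list alone (median -0.74, adjusted p = 2.36e-11). Of 23 red cell membrane genes 18 were lower and 4 higher, also adjusted over the list alone (median -0.53, adjusted p = 1.44e-09). All 5 globin genes were lower, 28 of 29 ribosome biogenesis genes were higher with 1 lower, and 22 of 25 mitosis genes were lower with 1 higher, each also adjusted over the list alone. Progenitor genes were higher at 13 of 25 and lower at 2, or 13 and 3 adjusted over the list alone (adjusted p = 1.37e-05). These 6 lists passed with an estimated correlation (adjusted p from 5.67e-04 for haem synthesis to 0.0484 for mitosis). Sterol synthesis was higher at 10 of 17 genes and lower at 3, also adjusted over the list alone (adjusted p = 8.08e-05; adjusted p = 0.131 with an estimated correlation), with Dhcr7 at 1.03 ± 0.04 and Lss at 0.78 ± 0.04. Mast cell genes were higher at 6 of 19 and lower at 1, also adjusted over the list alone (median -0.00, mean 0.58, adjusted p = 0.0102; adjusted p = 0.125 with an estimated correlation), with Tpsab1 at 3.08 ± 0.06 and Ndst2 at 1.25 ± 0.05. S phase genes were lower at 17 of 25, or 18 adjusted over the list alone (adjusted p = 1.51e-06; adjusted p = 0.125 with an estimated correlation). Glycolysis was higher at 11 of 17 genes and lower at 2, also adjusted over the list alone (adjusted p = 2.00e-05; adjusted p = 0.136 with an estimated correlation), with Hk2 at 1.86 ± 0.09. Erythroid regulators were lower at 14 of 26 and higher at 3, or 15 and 4 adjusted over the list alone (adjusted p = 0.003; adjusted p = 0.156 with an estimated correlation). Genes that restrain the cell cycle were lower at 10 of 21 and higher at 3, or 10 and 4 adjusted over the list alone (adjusted p = 0.0141; adjusted p = 0.131 with an estimated correlation). Autophagy genes were lower at 13 of 22 and higher at 4, or 14 and 4 adjusted over the list alone (adjusted p = 0.0102; adjusted p = 0.223 with an estimated correlation). Iron handling genes were lower at 8 of 15 and higher at 3, or 9 and 3 adjusted over the list alone (adjusted p = 0.015; adjusted p = 0.136 with an estimated correlation). The autophagy and iron handling calls were lost without replicate 3 of D218G (adjusted p = 0.12 and 0.0991) and with weighted arrays (adjusted p = 0.071 and 0.0973). The iron handling and mast cell calls were lost on ranks (adjusted p = 0.116 and 0.13), and the call for restraint of the cell cycle without moderation (adjusted p = 0.066). In all, 6583 genes differed, 3476 higher and 3107 lower in D218Y, and 301 by at least 2-fold (205 higher, 96 lower). Without replicate 3 of D218G the count was 9176 (3945 higher, 5231 lower). It was 10658 (4358 higher, 6300 lower) when arrays were weighted, which gave that array the lowest weight (0.21). Quantile normalization gave 3319 higher and 3371 lower, so the side with more calls turned in each of these.

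Between the mean of the D218 lines and the mean of the R216 lines, red cell and sterol genes were lower at D218 and ribosome biogenesis genes higher, but single lines carried much of this. Slc4a1 averaged 11.30 in D218G and 11.35 in R216Q, against 6.81 in D218Y and 12.29 in R216W, and Hba-x averaged 7.63 in D218G and 7.66 in R216Q. The ribosome biogenesis median against wild type was 0.41 in both D218G and R216Q. The sterol synthesis median was -0.36 in D218G (17 fell) and -0.13 in D218Y (8 fell, 4 rose). It was -0.01 in R216Q and 0.18 in R216W. The sterol genes Dhcr7 and Lss had their highest values of all lines in D218Y. Slc4a1 was at -2.77 ± 0.04 (SE, 6 arrays per side from 2 lines, adjusted p = 1.58e-15), Alas2 at -1.51 ± 0.04 and Hba-x at -1.26 ± 0.05. The SE and p-values of this contrast come from the spread between cultures of a line. They do not measure the spread between lines, so they do not tell a residue effect from line differences. Myb (0.92 ± 0.02) and Myc (0.72 ± 0.03) were higher, whereas Gata2 (0.07 ± 0.03) did not pass, with D218G (8.03) and D218Y (11.16) on either side of R216Q (9.48) and R216W (9.57). Pkhd1l1 (2.37 ± 0.04) had the largest rise among the genes named, and Il9r (-2.64 ± 0.03) and Cdc25b, a phosphatase that starts mitosis (-1.80 ± 0.03), were among those with the largest falls. All 17 sterol synthesis genes were lower at D218, also adjusted over the list alone (median -0.30, adjusted p = 7.61e-12). So were 17 of 23 red cell membrane genes with 2 higher, and 10 of 11 haem synthesis genes with Ppox higher (0.73 ± 0.03), both also adjusted over the list alone. Of 29 ribosome biogenesis genes 28 were higher and none lower, and of 21 genes that restrain the cell cycle 14 were lower and 2 higher, or 14 and 3 adjusted over the list alone. These 5 lists passed with an estimated correlation (adjusted p from 0.0053 to 0.0191). With the preset correlation alone, mitosis (17 of 25 lower, 2 higher; adjusted p = 8.27e-04; adjusted p = 0.303 with an estimated correlation) and autophagy (11 of 22 lower, 2 higher; adjusted p = 0.0017; adjusted p = 0.215 with an estimated correlation) were lower at D218. Globin genes (4 of 5 lower, adjusted p = 0.0014; adjusted p = 0.054 with an estimated correlation) were lower and progenitor genes (10 of 25 higher, 2 lower, adjusted p = 0.0057; adjusted p = 0.102 with an estimated correlation) higher. Megakaryocyte genes were lower at 6 of 19 and higher at 1 (adjusted p = 0.0397; adjusted p = 0.339 with an estimated correlation), a call that was lost after quantile (adjusted p = 0.0803) or cyclic loess normalization (adjusted p = 0.0769), on ranks (adjusted p = 0.0861), without moderation (adjusted p = 0.0564), with trend and robust moderation (adjusted p = 0.0524), with only these 12 arrays (adjusted p = 0.0509), with the array median as a covariate (adjusted p = 0.084), and without replicate 3 of R216W or replicate 1 or 3 of D218G (adjusted p from 0.0516 to 0.0599). Adjusted over the list alone, mitosis had 18 lower and the other counts were the same. In all, 6006 genes differed, 3243 higher and 2763 lower (3561 and 3608 when arrays were weighted), and 93 by at least 2-fold (50 higher, 43 lower). The arrays of the residues did not overlap for 1387 of the 6006 genes.

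The 4 mutants were also set against each other by the genes that each shared with another relative to wild type. R216Q and D218Y shared 2098 genes that were higher and 1609 that were lower, with 181 in opposite directions, and D218G and D218Y shared 1800 and 1264 with 188 opposite. R216Q and R216W shared 1117 and 844 with 250 opposite, R216Q and D218G 1362 and 972 with 176 opposite, and R216W and D218Y 1223 and 937 with 572 opposite. R216W and D218G shared 585 and 449, with 670 in opposite directions. Independent lists of the same lengths would share 192 higher and 112 lower genes for R216W and D218G, and 478 and 465 for R216Q and D218Y. Across genes, which are not independent replicates, fold changes of R216Q and D218Y had a correlation of 0.783 and those of R216W and D218G of 0.127. In 100 simulations of unchanged groups against the same wild type arrays, the mean correlation was 0.495 and 0.471 for these pairs and the highest 0.861 and 0.918, above both observed values. The simulated groups held no changes, so their correlations came from noise shared through the wild type arrays. They are thus no measure for pairs with real changes. The covariance shows the size of that shared noise, but it grows with the size of the changes and does not rank pairs by likeness. It was 0.0649 against a simulated mean of 0.0024 for R216Q and D218Y, and 0.004 against 0.0023 for R216W and D218G. The spread of the simulated covariances was not examined. The simulations gave a mean of 0.27 shared calls, and at most 27, for R216Q and R216W and 0 for every other pair. The wild type arrays could not be split so that each part kept 2, so a part of each overlap that comes from the shared controls is not ruled out.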

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

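The tests of D218G against R216Q and against R216W, and those of the probe sets left out of the comparisons, were chosen after the data were seen; the test of D218Y against D218G was fixed before.

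Gata2 moved in opposite directions in D218G and the other mutants. It fell by 0.29 in D218G and rose by 1.17 in R216Q, by 1.26 in R216W and by 2.85 in D218Y relative to wild type (log2, n = 3 arrays per line). The limma test of the difference gave -1.46 for D218G against R216Q (adjusted p = 2.87e-11), -1.54 for D218G against R216W (adjusted p = 2.69e-12) and 3.14 for D218Y against D218G (adjusted p = 1.73e-15).

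The sterol synthesis list rose in R216W (median 0.18, adjusted p = 2.87e-06; adjusted p = 0.123 with an estimated correlation) and fell in D218G (median -0.36). The difference, D218G against R216W, had a median of -0.61 over its 17 genes (camera, adjusted p = 1.63e-19; adjusted p = 0.0164 with an estimated correlation).

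Probe sets left out of the comparisons also held differences between D218Y and wild type. Of 1618 probe sets with several gene symbols 538 passed the limma test, 261 higher and 277 lower, and 19 changed at least 2-fold. Of 4952 probe sets with none listed 1227 passed, 494 higher and 733 lower, and 71 changed at least 2-fold.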

How the results depend on the processing

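The array median covariate and the comparisons without replicate 3 of D218G were chosen after the data were seen; the other alternatives were fixed before. Under all settings but those with each array left out in turn 190 recomputed counts stayed within 1.5 times and 18 moved further, all given here. Of the named genes, 6527 recomputed values kept their side of the threshold, 73 lost and 57 gained a call, and with each array left out in turn 4691 kept it, 132 lost and 13 gained one. A 2-fold threshold left, by construction, 100 genes for R216Q, 90 for R216W, 44 for D218G, 711 for D218Y, 76 for R216W against R216Q, 301 for D218Y against D218G and 93 for the D218 against the R216 mean. With an estimated correlation camera called 7, 2, 5, 7, 1, 6 and 5 lists in that order, where the preset correlation called 11, 11, 11, 14, 8, 14 and 10, since correlated genes carry less evidence. For R216W against R216Q fry, which tests a list by itself, called 13 lists, and genes above the median intensity gave 4; the cause of the latter was not tested. For the Bcl2 family in D218Y the direction reversed under fry (adjusted p = 0.0048), where camera compares with other genes and gave 0.942. Fitting the compared arrays alone gave 2106 genes for D218G and ended the Gata1 call in R216W (-0.11, adjusted p = 0.102). The main fit shares 1 estimate of a gene's spread over all lines. D218G had the largest spread within a line (median SD 0.08, against 0.05 to 0.06 in the others). The SE of the D218G contrasts may therefore be too small, but the cause of these changes was not tested. Array weights gave 10658 genes for D218Y against D218G; the cause was not tested.

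With each array left out in turn 165 counts stayed within 1.5 times, and genes called ranged from 3682 to 4100 for R216Q, 2657 to 3169 for R216W, 2931 to 3598 for D218G, 7220 to 9357 for D218Y, 2781 to 2955 for R216W against R216Q, 5542 to 9176 for D218Y against D218G, 5421 to 6385 for the D218 against the R216 mean and 7427 to 10042 for any difference. Lists ranged from 11 to 11, 10 to 12, 10 to 11, 13 to 14, 7 to 8, 12 to 14 and 9 to 10 in the same order of contrasts. Gata1 ranged from -0.21 to -0.20 in R216Q, -0.11 to -0.10 in R216W (call lost each time), -0.02 to 0.01 in D218G and -0.30 to -0.28 in D218Y.

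The replicate number as a block gave 4020, 2998, 3297, 8305, 3125, 6166 and 5648 genes in that order of contrasts. The numbers did not pair the arrays: of 30 same-number pairs 3 had deviations correlated above 0.1 (median -0.0247, range -0.505 to 0.407), and 2 of 15 arrays correlated best with their own number. Some arrays of other numbers did share deviations across lines (median over such pairs 0.0121). Replicate 3 of D218G correlated with replicate 2 of wild type (0.535) and of R216Q (0.519). The arrays of different lines thus did not all vary independently. The 3 arrays just named had the lowest array medians of their lines (6.24, 6.31 and 6.32). Replicate 2 of R216W did too (6.32), but it correlated with replicate 3 of D218G at 0.101. The cause, array-wide intensity among others, was not tested. Without replicate 3 of D218G, D218Y against wild type gave 10134 genes. Signal over background was not used here, so calls of dim genes are the least certain.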

Other observations

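Tests chosen after the result was seen were those on the Gata1 level, on mast cell genes, on low-oxygen genes in D218G and on splits of whole lines. The other splits, the array median test's prediction and the bounds of the other low-oxygen tests were fixed before their results were seen. The array median covariate was itself added after the data were examined, and the low-oxygen verdicts rest on more than the fixed bounds.

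Some genes set a single mutant apart from the other 3. At a change of at least 2-fold in 3 mutants and under 0.5 (log2) in the remaining one, D218G was the exception for 12 genes that were higher and 5 that were lower elsewhere, R216W for 4 and 8, and R216Q and D218Y for 0. These genes were chosen after their values were seen. D218G also had the fewest genes of at least 2-fold (44), which favours it as the exception under this rule. Those with D218G as the exception included Slc30a2 (3.38 in R216Q, 3.39 in R216W, -0.17 in D218G and 2.88 in D218Y), Tph1, Gata2, Bnip3 and Pgm1, an enzyme that links glycogen and glycolysis (1.05, 1.22, -0.05 and 1.58). Those with R216W as the exception included Slc22a4 (-2.27, 0.01, -2.42 and -3.49), Slc4a1, Slc14a1, Plek and Ctsl (1.11, -0.00, 1.46 and 1.16). The exception could still change by less than 0.5, as Gata2 did in D218G (-0.29) and Slc14a1 in R216W (0.43). Gask1b and Lgmn were at least 2-fold higher, and Gm5662, Gstt1 and Tubb1 at least 2-fold lower, in all 4 mutants. Over all sizes, 548 genes were called higher and 392 lower in all 4, with shared wild type arrays.

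Low-oxygen genes outside the glycolysis list were measured too. In D218Y Vegfa, a vessel growth factor, rose by 1.01 ± 0.05, Ero1a by 0.93 ± 0.05 and Egln1, an oxygen sensor, by 0.87 ± 0.07, while Pfkfb4, a regulator of glycolysis, fell by 2.13 ± 0.04 (SE, n = 3 arrays per line, limma adjusted p of 7.38e-08 or less). In R216W P4ha1, a collagen hydroxylase, rose by 0.74 ± 0.07 and Vegfa by 0.69 ± 0.05, while Pfkfb4 fell by 0.54 ± 0.04. Of 22 such genes 5 rose and 3 fell in R216W.

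D218Y differed from wild type at more genes of at least 2-fold (711) than R216Q (100), R216W (90) or D218G (44). Array medians ran from 6.24 to 6.41, so a shift of whole arrays was too small to make 2-fold changes. With the array median as a covariate D218Y still had 664 such genes against 100, 88 and 45, which the small shifts made likely beforehand. The D218Y medians (6.24 to 6.29) all lay below the wild type medians (6.31 to 6.41). The covariate is thus partly bound up with the line. The test does not cover smaller changes, and over all calls the side with more calls turned after cyclic loess normalization. A lower level of the GATA1 fusion could contribute in D218Y, where Gata1 was at -0.29, and no D218Y line with the wild type level was analysed here, so dose and mutation cannot be told apart there. In D218G Gata1 was at -0.0041 ± 0.03 while 3601 genes differed, but the probe set was not checked to separate the fusion from transcript of the disrupted allele, so a lower fusion level stays open there too. An effect of the mutation on the zinc finger remains a hypothesis, and differences between single lines stay open.

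Mast cell genes rose in D218Y, 7 of 19 measured. Mast cells mixed into the culture may account for this and cannot be excluded, and the list passed at adjusted p = 0.0391 but not with an estimated correlation (0.21), on ranks (0.143) or when these 6 arrays were fitted alone (0.0598). Of the genes measured, Tpsab1 changed by 3.06, Ms4a2 by 2.46 and Cpa3 by 0.65 in D218Y, while Fcer1a (-0.00) and Tpsb2 (-0.09) did not pass, and how much of each a contaminating cell would bring is not known here. Of the 19 genes 2 lay above the median of all genes in wild type (6.50). In D218Y Fcer1a (4.06), Tpsb2 (5.60) and Cpa3 (5.91) stayed below that value, while Tpsab1 (8.36) and Ms4a2 (6.56) rose above it. At such low values a missing rise of Fcer1a or Tpsb2 says little. Expression of mast cell genes by the D218Y cells themselves stays open as well. Mast cells could also bring the higher Tph1 in R216Q and R216W. Of the 6 other genes that rose in D218Y only 1, Hdc, rose in R216Q and 0 rose in R216W, within the bound of at most 1. Those genes were picked by their rise in D218Y, whose source is open, so their counts do not decide the source of Tph1.

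The glycolysis list was higher in all 4 mutants, and with an estimated correlation it passed in R216Q (adjusted p = 0.0382) and not in R216W (0.143), D218G (0.181) or D218Y (0.115). Low oxygen in dense cultures could be a source. The median of 22 low-oxygen genes was 0.0343 in R216Q (bootstrap 95% interval -0.0358 to 0.288), -0.0048 in R216W (-0.0489 to 0.0942), 0.0152 in D218G (-0.0538 to 0.118) and -0.0798 in D218Y (-0.156 to 0.293), against 0.531, 0.349, 0.164 and 0.569 for glycolysis. The bound was a median under 0.1, and all 4 met it, R216W with its whole interval. By that bound alone the values would have argued against low oxygen. But a median over genes that went both ways decides nothing, a judgement that was not part of the prediction. In R216Q 7 rose and 3 fell, in R216W 5 and 3, in D218G 5 and 1 and in D218Y 8 and 5. Low oxygen stays open in all 4, as does a direct effect of the mutations.

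The splits of the arrays bear on every count of calls. For R216Q, R216W, D218G and D218Y against wild type, R216W against R216Q and D218Y against D218G, 1 of the 10 splits of the 6 arrays, the real one, gave as many genes as the real 4283, 3308, 3601, 8857, 3369 and 6583, and the highest other split gave 0, 0, 1, 0, 0 and 0. For gene lists the real counts were 11, 11, 11, 14, 8 and 14, and the highest other split gave 12, 7, 10, 11, 6 and 11, so 2 of 10 splits were as large for R216Q and 1 of 10 for each other comparison. With 10 splits no share under 0.05 can be reached. For the D218 mean against the R216 mean, 1 of 100 splits of the 12 arrays gave as many genes (6006, highest other 3376) and 16 of 100 as many lists (10, highest other 15). Those splits break up the lines, so they decide nothing about the residues. Of the 3 ways to pair whole lines, 1 gave as many genes (6006, highest other 5696) and 3 gave as many lists (10, highest other 15), and 3 splits are too few for a share under 0.05. For the test of any difference among the lines, 1 of 100 assignments, the real one, gave as many genes (8347, highest other 4978). This share is under 0.05 and argues against chance, which 100 drawn assignments cannot exclude.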
